A study of Mus musculus with 12 samples.

How the data were processed

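RNA from mouse embryos at the early bud to head-fold stages was measured on 12 Illumina bead arrays in 4 groups of 3: anterior control, anterior Lhx1epiCKO, posterior control and posterior Lhx1epiCKO. Per the labels' protocols, each sample was a pool of 5 dissected embryo parts, and total RNA was extracted with a small-scale column kit before biotin labelling. The labels call the 3 samples of each group biological replicates, so the spread between arrays is the spread between pools. The labels do not say whether an anterior and a posterior pool of the same number came from the same embryos.

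The deposited table holds normalized log2 expression values made by the authors, with GenomeStudio and limma named in the submitters' processing notes and no version, role or order of steps. The method of normalization and of background correction is not given in the sources used here. In that table all 12 arrays had nearly the same distribution, with medians from 6.81 to 6.83 and a highest value of 14.8 on the log2 scale. The same deposited table gives a detection p-value for each probe and array, low where a probe was above background. A second deposited table holds the same log2 values, and the largest difference between them was 5.0e-09. Sample columns were matched to samples through their titles.

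The table holds 30344 probes with 19060 distinct gene names. Of these probes, 28034 had 1 gene symbol in the platform annotation, 0 had several and 2310 had none. The name in the file and the platform symbol gave the same gene for 27710 probes after symbols were updated. The 324 probes with differing names were tested but never named, and probes without a platform symbol kept the name in the file. Of the gene names in the file, 18991 were found in the reference gene table.

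Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, which left 17041 probes under 11470 gene names, and 9008 probes were detected on no array. All 12 arrays were fitted together in R 4.3.3 with limma 3.58.1, with 1 mean per group and no covariate, on the authors' values without further scaling. The linear model had 8 residual degrees of freedom, and the moderated variance added 4.87 prior degrees of freedom. The 5 contrasts were Lhx1epiCKO minus control in anterior samples, the same in posterior samples, the difference of these, and anterior minus posterior samples in controls and in Lhx1epiCKO embryos. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all probes tested. Every adjusted p of a gene is from this limma fit unless another setting is named.

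Lists of genes, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 32 lists. The test was repeated with an estimated correlation and with fry. The lists were anterior mesendoderm and prechordal plate, anterior neuroectoderm, node and notochord, primitive streak and nascent mesoderm, paraxial and presomitic mesoderm, definitive endoderm, extraembryonic visceral endoderm, cardiac mesoderm, blood and endothelium, extraembryonic mesoderm and allantois, extraembryonic ectoderm and trophoblast, surface ectoderm and amnion, epiblast and pluripotency, and primordial germ cells. Further lists were Hox genes, canonical WNT targets, WNT antagonists, the NODAL, BMP, FGF, retinoic acid and SHH pathways, neural crest and cranial mesenchyme, cell movement and adhesion, and the LIM-domain complex. The last were cell cycle, p53 targets and apoptosis, immediate early and heat shock genes, glycolysis and hypoxia, unfolded protein and amino acid response, ribosomal proteins and maternal decidua. Some genes belong to several lists. In these tests a gene was represented by its brightest probe.

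The genes named in the text followed a rule set before the data were examined: Lhx1, and for each contrast the 10 largest rises and 10 largest falls among called probes whose groups did not overlap. Where fewer than 10 passed in a direction, genes of smallest p filled the list up to 5. Up to 4 members of smallest p were named for each list, and 5 genes per direction for the difference of the genotype effects. Some genes that this rule picks are left unnamed. Other genes are said to be chosen after their values were seen. For a probe not above background on any array of a group, the fold is given as a lower bound, from the bright group's mean and the lowest signal of detected probes on the dim arrays. This bound holds for the measured means only. It takes no account of sampling error, so "at least" does not establish a minimum true change.

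The fit was tested on simulated data with 50 changed probes of each size among 17041. In the anterior genotype contrast, 32% of changes of 0.5 on the log2 scale, 90% of changes of 1 and 98% of changes of 1.5 were recovered. In the posterior genotype contrast these shares were 36%, 86% and 100%. For the difference of the genotype effects they were 4%, 64% and 92%. The anterior minus posterior contrasts recovered 90% of changes of 1 in controls and 90% in Lhx1epiCKO embryos. Among unchanged probes, between 5 and 12 were called per contrast. All simulated arrays had the same spread for a given probe. On the real arrays, deviations from the group mean had an SD from 0.077 (anterior Lhx1epiCKO replicate 1) to 0.358 (posterior Lhx1epiCKO replicate 3). The shares recovered are therefore not the power of the real comparisons. In a simulated set of 32 lists, camera called the 1 list that had been shifted and 0 others. The simulated genes were drawn independently of each other. This check therefore cannot show how often camera at the preset correlation calls unchanged lists of correlated genes.

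Alternatives set before the data were examined were quantile normalization of the deposited values, equal array medians, the second table, no filter or a stricter filter on dim probes, an intensity trend with robust variances, array weights, fits of the 6 arrays compared, the replicate number as a block, the pool as a block, an offset of 16, other thresholds, other ways to represent a gene in lists, and leaving out each array. Leaving out 2 posterior arrays together, dividing the anterior control arrays between both sides of a correlation, and leaving out each Lhx1epiCKO array from the correlations were chosen after seeing the data. The slide or position of an array was not given in the sources used here, so no test of it was run.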

Results

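Gene expression was measured in mouse embryos around the start of head formation. LHX1 is a LIM-domain homeobox transcription factor needed for the embryonic head. In Lhx1epiCKO embryos (Lhx1-/flox; Meox2+/Cre), Cre made from the Meox2 locus removes the remaining conditional Lhx1 allele in the epiblast, and control embryos (Lhx1+/flox; Meox2+/Cre) keep a wild-type allele. Controls carry Cre and a conditional allele as well, so their epiblast keeps only the wild-type allele. Tissue outside the epiblast also differs by genotype, since Lhx1epiCKO embryos carry the Lhx1- allele there. Anterior and posterior parts were dissected apart and pooled by 5, and each of the 4 groups had 3 arrays. The anterior control arrays detected 16047 ± 271 probes (SD, n = 3), and the anterior Lhx1epiCKO arrays 15761 ± 338. The posterior control arrays detected 14682 ± 192 probes and the posterior Lhx1epiCKO arrays 14446 ± 213. The number of arrays limits the precision of every value given here.

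The array labelled posterior Lhx1epiCKO replicate 3 stood apart from all others. On it 779 probes lay more than 1 log2 unit from the mean of the other two arrays of its group, 139 of them higher and 640 lower. Arrays of the other groups had between 0 and 35 such probes. Its 3 lowest values against the other two were Selenoh at 6.21 against 14.06, the apolipoprotein gene Apoa1 at 7.20 against 13.65 and the adenosine kinase gene Adk at 6.69 against 11.97, genes chosen after their values were seen. It stayed in the fit, and results that moved by over 1.5 times without it are named. The X-inactivation RNA Xist, which marks female tissue, read 7.87 ± 1.13 on anterior Lhx1epiCKO arrays and 10.22 ± 0.29 on anterior control arrays (SD, n = 3, adjusted p = 1), with no overlap, and was chosen after its values were seen.

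The first comparison checks the targeted gene. The only Lhx1 probe on the array read 8.13, 8.25 and 8.44 on the log2 scale on the anterior control arrays and 6.84, 6.65 and 7.09 on the anterior Lhx1epiCKO arrays. In posterior samples, control replicates 1 and 3 read 8.54 and 8.35, and the Lhx1epiCKO arrays read 6.85, 7.18 and 7.30. The array labelled posterior control replicate 2 read 6.90, within the range of the posterior Lhx1epiCKO arrays and against its label. The signal was not above background on anterior Lhx1epiCKO replicate 2 and posterior Lhx1epiCKO replicate 1. Whether the probe lies in the deleted part of the gene is not known here.

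**Figure D1:**
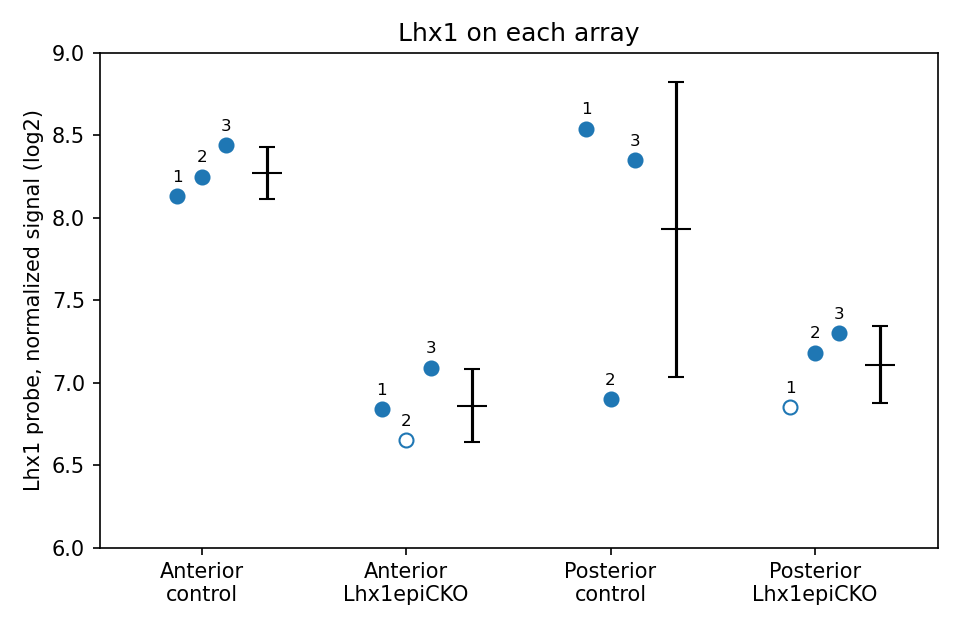
Normalized log2 signal of the Lhx1 probe on each of the 12 arrays, by group, with replicate numbers; open circles were not above background, and bars show the mean and SD of the 3 arrays. The anterior groups do not overlap, whereas the array labelled posterior control replicate 2 sits at 6.90, apart from the other two posterior controls.

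In anterior samples the Lhx1 difference was -1.41 ± 0.32 (log2, SE), a level 2.66-fold lower in Lhx1epiCKO, and the 3 Lhx1epiCKO arrays lay below the 3 controls. This difference did not pass over all probes, with an adjusted p of 0.344. Over the alternatives it ranged from -1.53 to -1.30, with adjusted p from 5.51e-05 to 1. It passed with array weights, in the fit of the 6 anterior arrays alone (adjusted p = 0.00168) and without the array labelled posterior control replicate 2 (-1.41, adjusted p = 0.00413). In posterior samples the difference was -0.82 ± 0.32, with an adjusted p of 0.504 and overlapping groups. It was -1.34 without the array labelled posterior control replicate 2 (adjusted p = 0.0614) and -0.52 without posterior control replicate 1, and over the alternatives its adjusted p ran from 0.00481 to 1.

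In the anterior embryo, 8 genes fell in Lhx1epiCKO embryos, Foxd4 and Shisa2 among them, and 4 rose, Gbx2 among them. Foxd4, a forkhead factor of the anterior neural plate, fell by 1.61 ± 0.19 on the log2 scale (SE, n = 3 per group), or 3.06-fold. Shisa2, whose family holds back WNT and FGF receptors, fell by 1.47 ± 0.15. The WNT receptor gene Fzd5 fell by 1.36 ± 0.14 and Shh, the signal of the prechordal plate and notochord, by 1.27 ± 0.18. Gbx2, a homeobox gene of the anterior hindbrain, rose by 1.24 ± 0.18, or 2.36-fold.

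This comparison asked which genes differ between the genotypes at the anterior end of the embryo. It called 12 probes of 12 genes, 4 higher and 8 lower in Lhx1epiCKO, with adjusted p from 0.0026 to 0.0355. Among those that rose were also the WNT receptor gene Fzd10 (1.20 ± 0.18) and Wnt8a, a WNT ligand of the primitive streak (1.08 ± 0.15), and not every called gene is named here. The secreted WNT inhibitor Sfrp1 fell by 1.08 ± 0.14 on the called probe, whereas its brightest probe read -1.20 ± 0.35 with an adjusted p of 1. Cadps2 fell by 0.95 ± 0.13, Nptx2 by 0.88 ± 0.14 and Srd5a2 by 0.69 ± 0.10. The WNT target Apcdd1 did not pass, at 0.60 ± 0.10 and an adjusted p of 0.0574 (range 0.000168 to 0.316 over alternatives). It passed with no filter on dim probes, array weights, the 6 anterior arrays alone and an offset of 16, without posterior Lhx1epiCKO replicate 3 and without both doubted arrays. At an unadjusted p under 0.05 there were 329 probes, against 852 from chance alone. That chance count assumes 1 spread for all groups, and the arrays differed in spread, so the lower count does not show a lack of change.

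Shisa2 and Fzd5 were called in all 24 alternative fits, and Foxd4 in all but the fit without anterior Lhx1epiCKO replicate 2 (adjusted p = 0.0552, with a range of 3.18e-06 to 0.0552 over alternatives). The number of called probes fell to 7, 4 and 5 without anterior control replicates 1, 2 and 3, and to 6, 2 and 5 without anterior Lhx1epiCKO replicates 1, 2 and 3. It fell to 4 without posterior control replicate 1 and to 6 without posterior control replicate 3, and rose to 42 without posterior Lhx1epiCKO replicate 3. With array weights 246 probes were called, with the 6 anterior arrays alone 58 and without both doubted posterior arrays 51.

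The other 9 called genes kept their direction in all 24 alternative fits, and each lost its call without single arrays. Posterior arrays enter this comparison only through the estimate of the spread, so leaving out a posterior array did not move the fold changes. Sfrp1 (-1.18 to -1.03 over alternatives) lost it without anterior control replicate 1 or 2 or any anterior Lhx1epiCKO array. Cadps2 (-1.10 to -0.80) did so without the same arrays or posterior control replicate 1. For Shh (-1.45 to -1.06) the arrays were anterior control replicate 3, any anterior Lhx1epiCKO array and posterior control replicates 1 and 3. For Srd5a2 (-0.74 to -0.62) they were any anterior array and posterior control replicate 1. For Nptx2 (-1.01 to -0.75) they were any anterior array but Lhx1epiCKO replicate 3, posterior control replicates 1 and 3 and posterior Lhx1epiCKO replicate 1. Among genes that rose, Wnt8a (0.91 to 1.19) lost its call without any anterior array but control replicate 1, or without posterior control replicate 1 or 3. Gbx2 (1.01 to 1.47) did so without any anterior array but control replicate 1, or any posterior control, and Fzd10 (1.07 to 1.36) without any anterior array but Lhx1epiCKO replicate 1, or any posterior control.

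**Figure D2:**
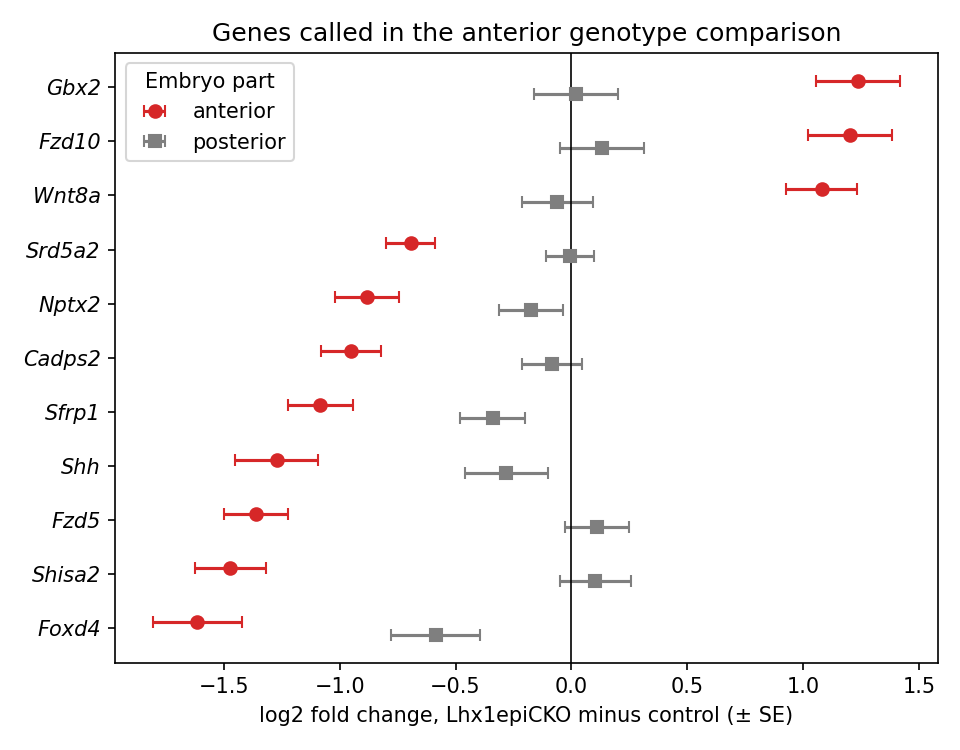
Log2 fold change of Lhx1epiCKO minus control, with SE, for genes called in anterior samples (circles; not every called gene is shown), and for the same probes in posterior samples (squares). Anterior values run from -1.61 for Foxd4 to 1.24 for Gbx2, and no posterior value was called.

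Primitive streak and nascent mesoderm genes were higher as a group in anterior Lhx1epiCKO samples. Of 26 measured members 22 had a positive difference, the median was 0.40 and camera gave an adjusted p of 3.26e-20. Over the alternatives, an estimated correlation and fry among them, the adjusted p of this list reached 0.029. Of these genes 1, Wnt8a, rose over all probes, and 10 rose and 1 fell adjusted over the list alone. Wnt3a, a ligand of the streak, read 1.80 ± 0.33 higher (adjusted p = 0.114), the mesoderm factor Tbx6 1.21 ± 0.20 (adjusted p = 0.0596) and the caudal homeobox gene Cdx1 1.55 ± 0.30 (adjusted p = 0.132). Paraxial and presomitic mesoderm genes were also higher, with a median of 0.09 over 15 members and an adjusted p of 6.98e-06, and 6 rose and 1 fell adjusted over the list alone. In that list Meox1, a somite homeobox gene, read 1.14 ± 0.23 (adjusted p = 0.163). Canonical WNT targets had a median of 0.21 over 20 members (adjusted p = 2.5e-10), with 6 higher and 1 lower adjusted over the list alone, among them the activin inhibitor Fst at 1.00 ± 0.17 (adjusted p = 0.0596).

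All 19 measured Hox genes, which pattern the trunk and hindbrain, had positive differences in anterior Lhx1epiCKO samples (median 0.15, mean 0.30, adjusted p = 9.64e-12). Adjusted over the list alone 3 members rose, with Hoxb1 at 1.20 ± 0.23 (adjusted p = 0.136) and Hoxa2 at 0.47 ± 0.10 (adjusted p = 0.223). Extraembryonic mesoderm and allantois genes had a median of 0.18 over 18 members (adjusted p = 2.24e-08). Of these 1 rose adjusted over the list alone, Cdx2, at 1.18 ± 0.24 (adjusted p = 0.157 over all probes). The retinoic acid list had a median of 0.07 over 14 members (adjusted p = 7.17e-05), with 3 higher and 1 lower adjusted over the list alone, and Aldh1a2, which makes retinoic acid, read 0.76 ± 0.20 (adjusted p = 0.627). Primordial germ cell genes had a median of 0.14 over 10 members (adjusted p = 0.00172) and BMP pathway genes one of 0.12 over 18 (adjusted p = 0.00374), and 0 members of either list passed over the list alone.

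Anterior mesendoderm and prechordal plate genes, the tissue beneath the forming forebrain, were lower as a group. Of 17 measured members 13 had a negative difference, the median was -0.34 and camera gave an adjusted p of 1.03e-14. Shh fell over all probes, and 9 members fell and 1 rose adjusted over the list alone. Cer1, a secreted inhibitor of NODAL, WNT and BMP signals, read -1.06 ± 0.21 (adjusted p = 0.163). Lhx1 itself belongs to this list. The forebrain homeobox gene Hesx1, above background on no anterior Lhx1epiCKO array, read at least 1.15-fold lower (adjusted p = 0.357).

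Definitive endoderm genes had a median of -0.16 over 19 members (adjusted p = 5.92e-07), and 4 fell adjusted over the list alone, with the hormone gene Trh at -0.88 ± 0.21 (adjusted p = 0.398). Anterior neuroectoderm genes had a median of -0.19 over 17 members (adjusted p = 0.000151). Foxd4 fell and Gbx2 rose over all probes, 4 members fell and 2 rose adjusted over the list alone, and Otx2, which marks forebrain and midbrain, read -1.20 ± 0.30 (adjusted p = 0.547). WNT antagonists had a median of -0.11 over 15 members (adjusted p = 0.000173), Shisa2 fell over all probes and 4 members fell adjusted over the list alone.

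In all, camera called 18 of the 32 lists in anterior samples, 12 higher and 6 lower, and fry called 6. Splits of the 6 anterior arrays that mixed the genotypes called up to 16 lists with camera. Small adjusted p-values at the preset correlation are therefore not a measure of chance. The 12 lists described so far kept their calls with an estimated correlation, where the smallest adjusted p was 0.0044, and the other 6 did not. Of those 12, several lost their call by fry. They were Hox genes (fry adjusted p = 0.0744), extraembryonic mesoderm (0.0501), retinoic acid (0.0702), germ cell (0.0563), BMP (0.0769) and anterior neuroectoderm genes (0.0563). Blood and endothelium genes had a median of 0.12 over 22 members (adjusted p = 3.33e-05), with adjusted p = 0.108 with an estimated correlation, and the embryonic globin gene Hbb-bh1 read 1.22 ± 0.40 (adjusted p = 1). Epiblast and pluripotency genes had a median of -0.17 over 19 (adjusted p = 9.15e-05), with adjusted p = 0.0977 with an estimated correlation, and the POU factor Pou3f1 read -0.63 ± 0.19. FGF pathway genes had a median of 0.10 over 17 (adjusted p = 0.00235), with adjusted p = 0.113 with an estimated correlation, and without anterior Lhx1epiCKO replicate 3 the call ended (adjusted p = 0.666, range 1.09e-05 to 0.666) and the median was -0.08.

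Cardiac mesoderm genes had a median of 0.09 over 20 members (adjusted p = 0.0235), with adjusted p = 0.213 with an estimated correlation. That call ended without anterior control replicate 2 (adjusted p = 0.55), anterior Lhx1epiCKO replicate 1 (0.307) or posterior Lhx1epiCKO replicate 3 (0.0653), with a range of 0.0019 to 0.55 over alternatives. The SHH list, with a median of -0.03 over 11 members and Shh as its 1 called gene, gave an adjusted p of 0.0456, with adjusted p = 0.193 with an estimated correlation. Its call ended without anterior control replicate 1 (0.0998) or 3 (0.239), anterior Lhx1epiCKO replicate 1 (0.0546) or 3 (0.255), the array labelled posterior control replicate 2 (0.054), and posterior Lhx1epiCKO replicate 1 (0.0713) or 3 (0.0653), and with the mean of all probes of a gene (0.0749), from a lowest value of 0.00361. Glycolysis and hypoxia genes had a median of 0.05 over 18 (adjusted p = 0.0464), with adjusted p = 0.0977 with an estimated correlation. Their call ended without anterior control replicate 1 (0.292), anterior Lhx1epiCKO replicate 2 (0.123) or 3 (0.177), the array labelled posterior control replicate 2 (0.054), posterior control replicate 3 (0.0504), and posterior Lhx1epiCKO replicate 2 (0.0846) or 3 (0.0653). It also ended with the mean of all probes (0.0989) and with quantile normalization (0.0536), from a lowest value of 0.0123, and without both doubted posterior arrays the cardiac (0.104), SHH (0.0938) and glycolysis (0.0714) calls ended.

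The remaining 14 lists were not called in anterior samples. Node and notochord genes had a median of -0.02 (adjusted p = 0.802), although Shh, a member, fell. The LIM-domain complex list, to which Lhx1 belongs, gave an adjusted p of 0.163 and NODAL pathway genes one of 0.738. Markers of other tissues that a dissected part could hold gave 0.674 for extraembryonic visceral endoderm, 0.712 for extraembryonic ectoderm and trophoblast, 0.565 for surface ectoderm and amnion, 0.857 for neural crest and cranial mesenchyme and 0.712 for maternal decidua. Cell movement and adhesion genes gave 0.552, cell cycle genes 0.74, p53 targets and apoptosis genes 0.371, immediate early and heat shock genes 0.701, unfolded protein and amino acid response genes 0.54 and ribosomal protein genes 0.882. In 5 of these lists the median, the mean and the test differed in sign, for example extraembryonic ectoderm with a median of -0.12 and a mean of 0.02, and this held for 0 called lists in any comparison.

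**Figure D3:**
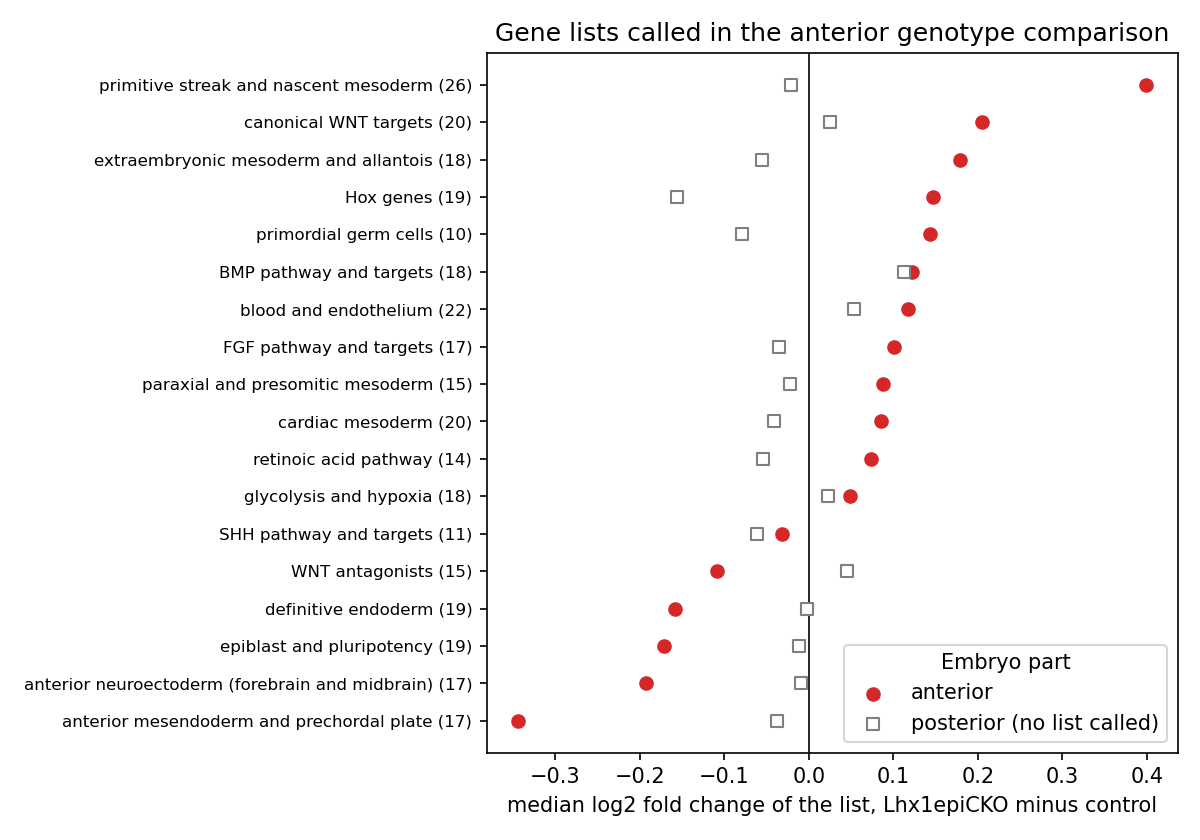
Median log2 fold change, Lhx1epiCKO minus control, of the 18 gene lists called in anterior samples, with the number of measured genes in brackets; filled circles are anterior and open squares posterior samples. The anterior medians run from -0.34 for anterior mesendoderm to 0.40 for primitive streak, and none of these lists was called in posterior samples.

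In the posterior embryo no gene passed the test between Lhx1epiCKO and control. The globin gene Hbb-bh1 read 1.49 ± 0.40 higher in Lhx1epiCKO on the log2 scale (SE, n = 3 per group, adjusted p = 0.481). The head homeobox gene Otx2 read -0.76 ± 0.30 (adjusted p = 0.506) and Foxd4 -0.59 ± 0.19 (adjusted p = 0.503). Among the genes of smallest p, Tmem33 read 0.67 ± 0.11, the cell cycle inhibitor Cdkn1a 0.52 ± 0.11 and Poldip2 0.54 ± 0.11, and the peptidase gene Nln, above background on no posterior control array, read at least 1.33-fold higher. On the lower side, Hnrnpd read -0.50 ± 0.10 and Gga1 -0.49 ± 0.09. Above background on no posterior Lhx1epiCKO array, 4933427D14Rik read at least 1.60-fold lower, Slc25a13 at least 1.24-fold and Igsf8 at least 1.16-fold, and each of these had an adjusted p of 0.481. These directions rest in part on the array labelled posterior control replicate 2.

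With limma 0 probes were called in posterior samples, and 1643 had an unadjusted p under 0.05, against 852 from chance alone. That chance count assumes 1 spread for all groups. Deviations from the group mean had an SD of 0.358 on posterior Lhx1epiCKO replicate 3 and 0.077 on anterior Lhx1epiCKO replicate 1. The excess can therefore not be read as a count of genotype effects. Array weights, the intensity trend with robust variances and the fit of the 6 posterior arrays also called 0. Without posterior Lhx1epiCKO replicate 1, Flot2 (-1.20) and Zc3h14 (-1.09) passed with an adjusted p of 0.0232. Without both doubted posterior arrays, an alternative chosen after seeing the data, 4 probes passed: Lhx1 (-1.43), Hbb-bh1 (2.23), Otx2 (-1.40) and Sfrp1 (-1.15). The array labelled posterior control replicate 2 was doubted for its Lhx1 value, so the Lhx1 call without it is not independent evidence. The array labelled posterior Lhx1epiCKO replicate 3 was doubted for its deviating probes. Otx2 read 8.48 on it, against 7.60 and 7.08 on the other posterior Lhx1epiCKO arrays, so the Otx2 call is not independent evidence either. Hbb-bh1 read 10.1 on the array labelled posterior control replicate 2, against 8.54 and 8.13 on the other posterior controls. Its call therefore also depends on the choice of arrays. The genes passing in these alternatives were named after their values were seen.

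No gene list was called in posterior samples, where the smallest camera adjusted p was 0.187, for extraembryonic visceral endoderm (median -0.16) and Hox genes (median -0.16), and fry called 0. On the array labelled posterior Lhx1epiCKO replicate 3, 6 of the 25 measured visceral endoderm genes lay more than 1 log2 unit below the other two arrays of its group. Without the array labelled posterior control replicate 2, visceral endoderm genes (median -0.26, adjusted p = 0.0163) and blood and endothelium genes (median 0.16, adjusted p = 0.028) were called. Without posterior control replicate 3, Hox genes were called (median -0.28, adjusted p = 0.000552). Without both doubted arrays, camera called 5 lists. Visceral endoderm (median -0.18, adjusted p = 0.00096), epiblast (-0.06, 0.0163), anterior mesendoderm (-0.06, 0.012) and anterior neuroectoderm (-0.02, 0.0431) were lower. Blood and endothelium (0.13, 0.0051) was higher. Otx2 belongs to the epiblast, anterior mesendoderm and anterior neuroectoderm lists, so these calls are not independent of the choice of arrays. Hbb-bh1 belongs to the blood and endothelium list, so the same holds for the calls of that list.

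A gene called in anterior and not in posterior samples is not thereby shown to differ between them, so the genotype effects were compared directly. Fzd5 (-1.47 ± 0.20) and Shisa2 (-1.58 ± 0.22) had the most negative difference of effects by p, with posterior changes of 0.11 ± 0.14 and 0.10 ± 0.15 and an adjusted p of 0.0561 for both. Next on that side were Cadps2 (-0.87 ± 0.18), Srd5a2 (-0.69 ± 0.15) and Grasp (-0.61 ± 0.13). On the positive side were Hoxb1 (1.80 ± 0.35, adjusted p = 0.442), the somite gene Meox1 (1.68 ± 0.33), Wnt8a (1.14 ± 0.22) and Gna14 (0.90 ± 0.17). For Lhx1 the difference of the effects was -0.59 ± 0.45 (adjusted p = 0.981). All these values include the array labelled posterior control replicate 2.

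With limma 0 probes were called for the difference of the genotype effects, and 581 had an unadjusted p under 0.05. Fzd5 passed with the intensity trend and robust variances (adjusted p = 0.0183), with array weights (0.0203), without anterior control replicate 3 (0.0206) and without posterior Lhx1epiCKO replicate 3 (0.019), with a range of 0.0183 to 0.29. Shisa2 passed with the intensity trend and robust variances and without posterior Lhx1epiCKO replicate 3 (-1.46, adjusted p = 0.019, range 0.0183 to 0.578), and so did Gna14 without that array (1.02, adjusted p = 0.0436, range 0.0436 to 1).

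By camera at the preset correlation 11 lists differed in genotype effect between anterior and posterior samples, 10 more positive and 1 more negative in anterior samples. The smallest adjusted p with an estimated correlation was 0.0724, so 0 of these calls held in that setting, and fry called 1, paraxial mesoderm (adjusted p = 0.0389). Without posterior Lhx1epiCKO replicate 1 the count was 7. The primitive streak list (median 0.39, adjusted p = 8.6e-10; adjusted p = 0.0907 with an estimated correlation) and Hox genes (median 0.34, adjusted p = 6.32e-09; adjusted p = 0.0922 with an estimated correlation) led the positive side. Adjusted over the list alone, 7 streak genes and 6 Hox genes passed. Anterior mesendoderm was more negative (median -0.27, adjusted p = 0.00073; adjusted p = 0.0907 with an estimated correlation), with 3 members past the threshold adjusted over the list alone.

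In control embryos, anterior and posterior parts differed in the genes that pattern the head and the trunk. Otx2 was 7.59-fold higher in anterior samples (2.92 ± 0.30 on the log2 scale, SE, n = 3 per group). The myosin gene Myl7 of the heart field (2.50 ± 0.34), Sfrp1 (2.43 ± 0.35), Shisa2 (2.29 ± 0.15), Cer1 (2.27 ± 0.21) and Foxd4 (2.23 ± 0.19) were also higher there. The ligand gene Wnt3a was 25.9-fold lower in anterior samples (-4.69 ± 0.33), followed by Cdx1 (-4.28 ± 0.30), Cdx2 (-3.12 ± 0.24), Hoxb1 (-3.02 ± 0.25) and Evx1 (-2.90 ± 0.26). Lhx1 did not differ past the threshold (0.34 ± 0.32, adjusted p = 0.77), with the array labelled posterior control replicate 2 included.

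This comparison asked which genes are regional in embryos that keep a wild-type Lhx1 allele. It called 513 probes, 231 higher and 282 lower in anterior samples, under 440 gene names of which 208 were higher and 232 lower. At an unadjusted p under 0.05 there were 2210 probes. Also among the largest were the POU factor Pou3f1 (2.11 ± 0.19), Slc7a3 (1.91 ± 0.26), Fzd5 (1.88 ± 0.14) and Utf1 (1.73 ± 0.23). On the posterior side were Fzd10 (-2.86 ± 0.18), Tbx6 (-2.81 ± 0.20), the galanin gene Gal (-2.81 ± 0.28), Mixl1 (-2.80 ± 0.31) and T, which marks the streak (-2.63 ± 0.41). All 20 of these kept their calls in every alternative fit.

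The count of called probes was 302, 276 and 319 without anterior control replicates 1, 2 and 3, 300 without the array labelled posterior control replicate 2 and 906 without posterior Lhx1epiCKO replicate 3. With array weights it was 1013, and 154 of the 513 had a log2 fold change of at least 1. Some genes were above background on no anterior control array: Hoxa5 was at least 5.23-fold lower there, the allantois gene Tbx4 at least 4.89-fold and Cdx4 at least 2.08-fold.

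In controls camera called 14 lists, 4 higher and 10 lower in anterior samples. Of 26 primitive streak genes 20 were lower and 0 higher in anterior samples, and 23 were lower adjusted over the list alone (median -1.56, adjusted p = 9.82e-44). Of 19 Hox genes 14 were lower (15 adjusted over the list alone, median -1.13), and of 20 WNT targets 12 were lower and 1 higher (13 and 1 adjusted over the list alone). Higher in anterior samples were 7 of 19 definitive endoderm genes (median 0.32), 5 of 19 epiblast genes with 1 lower (median 0.36), 6 of 17 anterior neuroectoderm genes with 2 lower (median 0.38), and 6 of 17 anterior mesendoderm genes with 1 lower (median 0.35).

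Of these calls in controls 12 held with an estimated correlation. The retinoic acid list (adjusted p = 0.000306) had adjusted p = 0.0608 with an estimated correlation. The NODAL list (adjusted p = 0.0334) had adjusted p = 0.0734 with an estimated correlation, and its call also ended without posterior control replicate 1 (0.0831) or 3 (0.0585), without both doubted arrays (0.0583) and with the mean of all probes (0.051), from a lowest value of 0.00491. The FGF, extraembryonic mesoderm, germ cell, paraxial mesoderm and cell movement lists were lower in anterior samples and held. By fry, which tests a list without setting it against other genes, 17 lists passed.

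In Lhx1epiCKO embryos the same regions were compared. Otx2 was 5.58-fold higher in anterior samples (2.48 ± 0.30 on the log2 scale, SE, n = 3 per group), and the Iroquois homeobox genes Irx5 (1.91 ± 0.18) and Irx3 (1.82 ± 0.27) and the POU factor Pou3f1 (1.80 ± 0.19) were higher there too. Wnt3a was 7.54-fold lower in anterior samples (-2.92 ± 0.33), with Cdx1 (-2.80 ± 0.30), Evx1 (-2.64 ± 0.26), Mixl1 (-2.29 ± 0.31) and Tbx4 (-2.17 ± 0.22). Lhx1 read -0.25 ± 0.32 (adjusted p = 0.779).

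The comparison called 216 probes, 71 higher and 145 lower in anterior samples, under 191 gene names, 67 higher and 124 lower, with 2094 at an unadjusted p under 0.05. Also named were Sox21 (1.47 ± 0.18), Foxd4 (1.20 ± 0.19), Fgf17 (-2.04 ± 0.14), Cdx2 (-2.03 ± 0.24), Chst7 (-1.92 ± 0.14), Hoxa5 (-1.90 ± 0.16) and Tbx6 (-1.85 ± 0.20). The count was 96, 121 and 139 without anterior Lhx1epiCKO replicates 1, 2 and 3 and 385 without posterior Lhx1epiCKO replicate 3. In the fit of these 6 arrays alone it was 64, where Mixl1 lost its call, 68 had a log2 fold change of at least 1, and without both doubted arrays it was 425.

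Some calls in Lhx1epiCKO embryos ended when single arrays were left out. Control arrays enter this comparison only through the estimate of the spread, so leaving out a control array did not move the fold changes. Sfrp1 (1.64 ± 0.35) lost its call without any array other than posterior Lhx1epiCKO replicate 3, with values from 1.30 to 1.68, and with no filter on dim probes, with the intensity trend and robust variances and in the fit of the 6 arrays alone. Myl7 (1.92 ± 0.34) and Slc7a3 (1.45 ± 0.26) lost theirs without anterior Lhx1epiCKO replicate 1 (1.86 and 1.52), anterior Lhx1epiCKO replicate 3 (1.89 and 1.34) or posterior Lhx1epiCKO replicate 2 (1.66 and 1.27), and in the fit of the 6 arrays alone. Dnmt3l (1.20 ± 0.24) lost its call without anterior control replicate 2 or posterior control replicate 1 (1.20 in both), anterior Lhx1epiCKO replicate 1 (1.32) or 3 (0.90), or posterior Lhx1epiCKO replicate 1 (1.16) or 2 (1.25), with no filter on dim probes (1.20), with array weights (1.10) and in the fit of the 6 arrays alone.

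Camera called 12 lists between the regions of Lhx1epiCKO embryos, 4 higher and 8 lower in anterior samples, and fry 15. Streak genes (16 of 26 lower, 21 adjusted over the list alone, median -1.16), Hox genes (11 of 19 lower, 15 adjusted over the list alone, median -0.76), WNT targets, FGF pathway genes, NODAL pathway genes and definitive endoderm genes kept their calls with an estimated correlation. Cardiac mesoderm (median 0.28) and anterior neuroectoderm (median 0.16) each had adjusted p = 0.0791 with an estimated correlation. Epiblast genes (median 0.22) had adjusted p = 0.109 with an estimated correlation and extraembryonic mesoderm (median -0.20) adjusted p = 0.0907 with an estimated correlation. The retinoic acid list (median -0.25) had adjusted p = 0.136 with an estimated correlation. Germ cell genes (median -0.21) had adjusted p = 0.0515 with an estimated correlation and lost their call without posterior Lhx1epiCKO replicate 2 (0.058, range 0.000598 to 0.058). Anterior mesendoderm genes were not called here (median 0.13, adjusted p = 0.351), with 2 of 17 higher and 1 lower, and neither were WNT antagonists (median 0.13, adjusted p = 0.395).

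The genes called in the anterior genotype comparison were also called between the regions of controls. All 8 called lower, such as Foxd4, Shisa2 and Fzd5, were called higher in anterior than posterior control samples, where independent lists would share 0.108. All 4 called higher, such as Gbx2, Fzd10 and Wnt8a, were called lower there, where independent lists would share 0.0662. Both comparisons use the anterior control arrays, so the values for independent lists are not the chance level of this overlap. Between the regional comparisons in controls and in Lhx1epiCKO embryos, 54 probes were higher in anterior samples in both (0.962 for independent lists), 138 were lower in both (2.4) and 0 went opposite ways (3.14).

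Across the 17041 probes, which are not independent replicates, the anterior genotype difference correlated at -0.624 with the regional difference of controls. Unchanged groups simulated 100 times with the same shared controls gave -0.497, and the covariance was -0.0212 against -0.0128 simulated. With the anterior control arrays divided, so that no array was on both sides, the correlation was -0.308, -0.445 and -0.278 with replicate 1, 2 or 3 kept for the genotype difference, a setting chosen after seeing the data. The posterior genotype difference correlated at -0.633 with the regional difference in Lhx1epiCKO (simulated -0.498; covariance -0.0363 against -0.0129). Without posterior Lhx1epiCKO replicate 3 that value was -0.488, against -0.598 simulated (covariance -0.0195 against -0.0193), and without both doubted arrays -0.481, against -0.545. With the regional difference in controls it correlated at 0.169 (simulated 0.5; covariance 0.00987 against 0.0129), and at 0.268 without posterior control replicate 1 (simulated 0.6). The anterior and posterior genotype differences, which share no array, correlated at 0.118 (simulated 0.003; covariance 0.00339 against 7.49e-05). That value was 0.061 without anterior Lhx1epiCKO replicate 2, 0.019 without posterior Lhx1epiCKO replicate 2, 0.244 without posterior Lhx1epiCKO replicate 3 and 0.267 without both doubted arrays.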

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

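The tests of the array labelled posterior Lhx1epiCKO replicate 3, of a swap, of Xist, of mixed tissue and of younger embryos were chosen after the result was seen; the splits of the arrays and the test for Lhx1epiCKO embryos under a control label were set beforehand.

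The genotype effect differed between anterior and posterior samples for 11 gene lists, by a test of the difference itself with a preset correlation between genes, and 0 of these calls held with an estimated correlation. The median difference of the log2 effects was 0.385 for primitive streak genes, 0.341 for Hox genes, 0.239 for paraxial mesoderm, 0.237 for extraembryonic mesoderm, 0.209 for WNT targets and -0.273 for anterior mesendoderm, and these 6 kept the call without any one array. It was 0.234 for germ cell genes, whose call ended without anterior control replicate 3 (adjusted p = 0.0587), anterior Lhx1epiCKO replicate 3 (0.0579) or posterior Lhx1epiCKO replicate 1 (0.081), in a range of 0.00541 to 0.0985. It was 0.154 for the FGF list, whose call ended without anterior Lhx1epiCKO replicate 3 (0.252) or posterior Lhx1epiCKO replicate 1 (0.0618), in a range of 0.00114 to 0.321. It was 0.141 for visceral endoderm, whose call ended without anterior control replicate 1 (0.172), anterior Lhx1epiCKO replicate 3 (0.0648), posterior control replicate 1 (0.298) or 3 (0.064), or posterior Lhx1epiCKO replicate 2 (0.118), in a range of 0.000148 to 0.321. For the retinoic acid list it was 0.038, and the call ended without anterior control replicate 2 (0.0626), anterior Lhx1epiCKO replicate 2 (0.0705), posterior control replicate 1 (0.0909) or 2 (0.168), or posterior Lhx1epiCKO replicate 1 (0.0861) or 2 (0.0983), in a range of 0.00541 to 0.254. For cell movement genes it was 0.072, and the call ended without anterior control replicate 2 (0.0654), anterior Lhx1epiCKO replicate 3 (0.0834), posterior control replicate 3 (0.128), or posterior Lhx1epiCKO replicate 1 (0.0809) or 2 (0.112), in a range of 0.00999 to 0.128.

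Of 100 splits within each region, drawn from 200 possible ones, 4 gave at least 11 lists, the real one included, with 13 the highest of the others. That share is under 0.05 among the splits drawn, at the preset correlation alone, and the count was 7 without posterior Lhx1epiCKO replicate 1 and 0 with an estimated correlation. For probes the real count by limma was 0, with 581 at an unadjusted p under 0.05, so all 100 splits reach it whatever the data hold and the count decides nothing about chance. The highest of the others gave 14. For the comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05. In anterior samples the genotype split gave 12 probes and 18 lists, against at most 0 and 16 in the other splits, and 1 of the 10 splits gave as many. In posterior samples it gave 0 probes and 0 lists, against at most 0 and 4, and 10 of 10 gave as many. Between regions it gave 513 probes and 14 lists in controls, against at most 0 and 11, and 216 probes and 12 lists in Lhx1epiCKO, against at most 19 and 4, with 1 of the 10 splits giving as many.

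The first pattern is that anterior Lhx1epiCKO samples lay closer to posterior samples, with head genes lower and streak and Hox genes higher. Posterior tissue mixed into these pools by a shifted dissection plane would need a share of 43.9% for the 41 probes higher in anterior controls. For the 113 lower ones it would need 17.9%. These shares take the added tissue to have the mean composition of the posterior control pools. Tissue next to the dissection plane was not measured and may differ from that mean, so a shifted plane as the sole cause stays open. The shares differed by 25.9 points (interval 14.8 to 47.9). This argues only against average posterior tissue as the sole cause of both the fall of head genes and the rise of posterior genes. That interval comes from resampled probes, not pools, and the probes were chosen with the same anterior control arrays. A smaller share of posterior tissue would also lower head genes, so mixing as part of the cause of their fall stays open. For the rise of posterior genes mixing stays open, since 10.6% of the 113 probes lay over 2 standard errors from a single share per pool. Younger Lhx1epiCKO embryos would have lower Hox genes and higher epiblast genes. In anterior samples both went the other way. The median of the 19 measured Hox genes was 0.147 there, with all 19 positive. Epiblast genes had a median of -0.172 (camera adjusted p = 9.15e-05, and 0.0977 with an estimated correlation). In posterior samples the Hox median was -0.156 with 14 negative (camera adjusted p = 0.187), so younger embryos stay open. An effect of the genotype on the tissues themselves, a hypothesis here, and older Lhx1epiCKO embryos, which were not tested, remain open.

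The second pattern is the low Lhx1 signal on the array labelled posterior control replicate 2. A swap with a posterior Lhx1epiCKO array is argued against, because the highest of those read 7.3 and the lowest other posterior control 8.35. Its Xist signal differed from that of anterior control replicate 2 by -2.75, against at most 0.45 in size in the other 5 pairs, so its pool may hold other embryos than its anterior namesake, if pools of one number otherwise share embryos, which the labels do not say. Whether it held Lhx1epiCKO embryos stays open. Its deviation from the other posterior controls correlated at 0.316 with the posterior Lhx1epiCKO mean minus those same controls. The same calculation on those controls gave 0.351 and 0.311. Each correlation has the same controls on both sides, which alone gives a positive value, so it cannot decide the question. No biological explanation was tested for this array.

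The third pattern is the array labelled posterior Lhx1epiCKO replicate 3 standing apart. More anterior tissue in its pool is argued against as the cause of most deviating probes. Of these, 2.3% differ between regions of controls (18 of 779, beside 513 of all 17041 probes). Probes higher and lower in anterior controls deviated by medians of 0.081 and -0.038, which differ by 0.119. Both medians lie in the direction of anterior tissue, so a small share of it stays open. A loss of visceral endoderm from the pool is argued against as well, with a median deviation of 0.245 (interval -0.215 to 0.487) over 25 of its genes, although 6 of these lay lower by over 1. Among genes with a second probe, that probe deviated in the same direction for 42.9% (160 of 373, interval 37.8 to 48.1), so a failure of single probes on this array is consistent with the values. No biological explanation was tested for this array.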

How the results depend on the processing

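Leaving out both doubted posterior arrays, dividing the anterior controls and leaving out Lhx1epiCKO arrays from the correlations were chosen after seeing the data. Among values of named genes over the alternatives, 1699 stayed on the same side of the threshold, 13 came to pass it and 101 ceased to, and among values of the lists called as designed 945 stayed and 100 ceased to pass. None of the calls was replaced by a call in the other direction, although some values past no threshold changed sign. The second deposited table, quantile normalization, equal medians, the offset and the filters on dim probes moved none of the counts of called probes by over 1.5 times. Dim signals limit the bounds given for undetected probes, and the slide as a block was not run because it was not given. Where values moved, the cause was not tested, apart from the fits with fewer arrays or a looser or stricter threshold. In anterior samples the genotype comparison called 246 probes with array weights, 58 with only its 6 arrays, 51 without both doubted arrays and 329 at an unadjusted p under 0.05. Without one array each it called 2 (without anterior Lhx1epiCKO replicate 2) to 42 (without posterior Lhx1epiCKO replicate 3). The posterior comparison called 4 without both doubted arrays, 1643 unadjusted and 0 to 2 (without posterior Lhx1epiCKO replicate 1) without one array each. The difference of the genotype effects called 2 with the intensity trend and robust variances, 1 with array weights, 581 unadjusted and 0 to 3 (without posterior Lhx1epiCKO replicate 3) without one array each. Between regions of controls the counts were 1013 with array weights, 154 at a log2 fold change of at least 1, 2210 unadjusted and 276 (without anterior control replicate 2) to 906 (without posterior Lhx1epiCKO replicate 3) without one array each. Between regions of Lhx1epiCKO embryos they were 64 with only the 6 arrays compared, 425 without both doubted arrays, 68 at a log2 fold change of at least 1, 2094 unadjusted, and 96 (without anterior Lhx1epiCKO replicate 1) to 385 (without posterior Lhx1epiCKO replicate 3) without one array each. Lhx1 in anterior samples passed with array weights (-1.38), with only the 6 arrays (-1.41) and without both doubted arrays (-1.41), and ran from -1.53 to -1.31 without one array each. In posterior samples it passed without both doubted arrays (-1.43) and ran from -1.34 to -0.52 without one array each. Lists called in anterior samples were 6 with fry and 15 to 18 without one array each. In posterior samples they were 5 without both doubted arrays and 0 to 2 (without the array labelled posterior control replicate 2) without one array each. For the difference of effects they were 0 with an estimated correlation, 1 with fry, and 7 (without posterior Lhx1epiCKO replicate 1) to 14 without one array each. Between regions they were 13 to 15 in controls without one array each, and in Lhx1epiCKO 6 with an estimated correlation and 11 to 14 without one array each.

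The correlation of the anterior genotype difference with the regional difference of controls was -0.308, -0.445 and -0.278 with anterior controls divided, as no array was then shared, and -0.66 to -0.537 without one array each (-0.598 to -0.444 for simulated unchanged groups, so this range does not show stability). That of the posterior genotype difference with the regional difference of Lhx1epiCKO was -0.481 without both doubted arrays (-0.545 for simulated unchanged groups) and -0.783 (without posterior Lhx1epiCKO replicate 1; -0.599 simulated) to -0.488 (without replicate 3; -0.598 simulated) without one array each. That of the 2 genotype differences was 0.267 without both doubted arrays and 0.019 (without posterior Lhx1epiCKO replicate 2) to 0.244 (without posterior Lhx1epiCKO replicate 3) without one array each. With the replicate number as a replicate block, the anterior genotype comparison called 8 probes and the posterior one 0, the difference of effects 0, and the regional comparisons 459 in controls and 208 in Lhx1epiCKO, with 18 lists in anterior samples. As a check, deviations of arrays with the same number correlated at 0.241, 0.047 and 0.019 between anterior groups, at 0.031, 0.009 and 0.005 between posterior groups, at -0.003, -0.041 and 0.024 between regions of controls and at 0.068, 0.246 and 0.079 between regions of Lhx1epiCKO. Between regions, each array correlated best with its own number in Lhx1epiCKO, and in controls only replicate 3 did. Groups of different genotype hold different embryos and do not bear on this. Xist differed by at most 0.45 within such pairs, apart from control replicate 2 (-2.75). Pairing of regions by number stays open and was not used in the main fit. With the pool as a block, the regional comparisons called 373 probes in controls and 176 in Lhx1epiCKO, and the difference of effects 0.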

Other observations

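The genes of this part were chosen after their values were seen. The embryonic globin gene Hbb-bh1 read 8.11, 8.01 and 8.19 on the anterior control arrays and 9.02, 9.39 and 9.55 on the anterior Lhx1epiCKO arrays. On the posterior Lhx1epiCKO arrays it read 11.07, 10.06 and 10.12, and on the posterior controls 8.54, 10.1 and 8.13, where the array labelled posterior control replicate 2 holds the highest value. Otx2 read 8.79, 7.94 and 8.69 on the posterior controls and 7.60, 7.08 and 8.48 on the posterior Lhx1epiCKO arrays, and here the array labelled posterior control replicate 2 holds the lowest control value. Elf5, a marker of extraembryonic ectoderm, was above background on all 6 anterior arrays, at 6.82 to 8.90 on its brighter probe, and on 0 posterior arrays.

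Xist, by its brightest probe, read 9.90, 10.47 and 10.28 on the anterior controls and 8.39, 6.57 and 8.65 on the anterior Lhx1epiCKO arrays. In posterior samples it read 10.08, 7.72 and 9.83 on the controls and 8.24, 6.71 and 9.06 on the Lhx1epiCKO arrays. It was not above background on Lhx1epiCKO replicate 2 of either region. Eif2s3y, which lies on the Y chromosome, read 8.43 ± 0.37 on the anterior controls and 9.09 ± 0.15 on the anterior Lhx1epiCKO arrays (SD, n = 3). In posterior samples it read 8.33, 8.93 and 7.91 on the controls and 8.60, 8.72 and 8.72 on the Lhx1epiCKO arrays. Neither Xist nor Eif2s3y passed the limma test between genotypes.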
